A study of Homo sapiens with 24 samples.

How the data were processed

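The data were RNA-seq libraries of an H358 clone with a doxycycline-inducible Zeb1-mCherry cDNA. Per the labels, RNA was extracted with TRIzol from untreated cells and on days 1 to 7 of doxycycline, 3 libraries per group and 24 in all, and libraries were made with a stranded poly(A) kit and sequenced paired-end. TopHat 1.4.1, Cuffdiff 2.2.0 and genome build hg19 are named in the submitters' processing notes; the annotation release and the settings are not given in the sources used here. FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments) were computed and deposited by the authors, per the file headers as 1 column per day.

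The deposited table has 57195 features with Ensembl identifiers and hg19 coordinates and 8 value columns for 24 libraries. In each column, for 31.0 to 33.3% of values over 1 FPKM, 3 times the value had at most 6 decimals (within a tolerance of 0.001 of a millionth of an FPKM), against 10.5 to 11.5% for the value itself and 10.3 to 11.4% for 7 times the value. Most values do not meet this. Each column was read as the authors' mean of the 3 libraries of a day from this excess and from the 8 columns for 24 libraries, and the table itself does not state it. Estimates of the 3 libraries were not used here, so no standard deviation, no test between 2 days and no blocked or leave-one-library-out fit could be made. Cuffdiff spreads fragments over transcripts by a statistical model, so values of overlapping genes and near-identical copies are uncertain, and an exact 0 can be a failed estimate of a locus. Mitochondrially encoded genes were not analysed here.

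The tests planned before the data were examined compared the 3 libraries of each day with the untreated libraries. The table holds 1 value per day, read as a mean, so other tests were chosen after it was seen. Features were kept when they reached 1 FPKM on at least 1 day. Short RNA classes (names of microRNA, small nucleolar, Cajal body, small nuclear, 7S, 5S and Y RNA features), 324 of them reaching 1 FPKM, were left out, and of entries sharing a symbol the one with the highest mean was kept. A further 72 features were listed at 0 on 1 to 7 days and at 1 FPKM or more on all remaining days. They were left out as possible failed estimates, a rule also made after the table was seen. This left 15421 features, of which 12352 are protein coding and 14904 (96.6%) have a transcript length in GENCODE release 29, which was used only for gene type, longest transcript length and GC content by Ensembl identifier.

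Fold changes are differences of log2(FPKM + 1), and counts of features at least 2-fold different (1 on this scale) carry no test. The trend test was a linear regression of log2(FPKM + 1) on day, fitted with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend, 6 residual degrees of freedom before moderation, 2-sided) and adjusted by Benjamini-Hochberg over all tested features at 0.05. Its error is the scatter of 8 means around a straight line, not replicate error, so a feature with a step or a peak has a large error, and neighbouring days need not be independent. Simulated data with the same features and residual spread were drawn independently between genes and between days. Trends were added to features with a mean log2(FPKM + 1) over 1. The test recovered 93.9% of 66 4-fold trends over the course, 56.7% of 67 2-fold and 10.4% of 67 1.5-fold trends. Of 15421 genes run, 5 without an added trend were called. The simulation holds no dependence between neighbouring days, so it does not give the rate of false calls in the real data. An exact Spearman test over all orders of the 8 days was added.

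Gene lists fixed before the data were examined covered adherens and tight junctions, desmosomes, keratins, epithelial transcription factors, other epithelial genes, mesenchymal markers, EMT transcription factors, collagens and matrix, the hemidesmosome and its laminin, integrins, extracellular proteases and inhibitors, EMT splicing regulators, SR and hnRNP proteins, signalling, lung lineage, cell cycle, metabolism, stress, immune and other cell type lists, 36 in all. Lists with at least 5 tested members were tested on the day trend with limma's camera (preset correlation 0.01), with camera's estimated correlation and limma's fry as alternatives, and adjusted by Benjamini-Hochberg over the lists. List medians were also placed among 10000 random lists of the same size matched on mean expression in 20 bins.

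Named genes followed a rule written before the data were examined and adapted to means. They are the 10 largest rises and falls on day 7 among features with a called trend, the 10 largest increases and decreases on day 1, the 3 largest of each step from day 2, the 5 largest increases and decreases on days 1 to 6 with less than 50% left on day 7, and up to 4 called members of each list. ZEB1, CDH1, CDH2, VIM, FN1, EPCAM and all tested EMT transcription factors and EMT splicing regulators were to be named whatever their values. Some genes that the rule names are not given. The planned rule also required calls for days and steps, which means cannot give. The rule passes over features named after clones and features of the Y chromosome; 2 features with clone names are given among those left out of the comparisons. Levels of untested list members and of left-out features were chosen after their values were seen.

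Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, median centring, quantile normalization, eBayes without trend or with robust estimation, weights per day, short RNA features kept, and entries sharing a symbol summed. Chosen after the table was seen were the exact Spearman test, keeping features listed at 0, leaving out each day in turn or days 5 and 6, and removing in each day the trend of log2 values with transcript length and GC content (natural splines with 4 degrees of freedom each). Median centring and quantile normalization shifted the median change of all tested features by at most 0.08 and 0.04 on the log2 scale, and that median lay between 0.01 and 0.06 on every day.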

Results

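RNA from H358 cells, an established human lung cancer line, was profiled over 7 days of doxycycline. The cells were a clone carrying a doxycycline-inducible Zeb1-mCherry cDNA, and the stated purpose of the course was to follow cells through epithelial-to-mesenchymal transition (EMT). ZEB1 is a zinc-finger repressor of epithelial genes and a known driver of EMT. There were 8 groups of 3 libraries each, untreated (no Dox) and days 1 to 7, from poly(A)-selected, stranded, paired-end sequencing. The deposited table lists 57195 Ensembl features with 1 FPKM value per group, read here as the authors' mean of its 3 libraries, which the table does not state. No spread between the 3 libraries of a day can be given, and no day carries a replicate error. FPKM summed to between 541506 on day 7 and 632619 on day 5, and between 14245 features in untreated cells and 14669 on day 4 reached 1 FPKM. Read counts per library were not used here, so the depth behind each value is unknown. Untreated cells were sampled at a single time, and doxycycline, ZEB1 induction and days in culture changed together.

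In the 15421 features tested, changes are given as differences of log2(FPKM + 1), which understates the change of low features. The words rose and fell are kept for features with a straight-line slope over the 8 days that limma's test called (adjusted p under 0.05). The spread in it is the scatter of the 8 means around the line, and how well a line described the values was not tested. By limma's test 1822 features rose and 1806 fell, with 5716 at an unadjusted p under 0.05. An exact Spearman permutation test over all orders of the days called 789 up and 933 down, and 1594 features were called by both tests in the same direction. The 2 limma counts depended on the days included. They were 636 and 804 without the untreated mean, 1044 and 1276 without day 1, 1030 and 1117 without day 6, 2801 and 2374 without day 7, and 1229 and 1255 without days 5 and 6.

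For named genes and lists, the alternatives that ended a call are given with the range of their adjusted p, where days joined by or were left out in turn. Losses of single genes in the exact Spearman test are given only as a number.

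The induced gene was examined first. ZEB1 (ENSG00000148516, chromosome 10, 31607424 to 31818742 on hg19, plus strand) was at 1.77 FPKM in untreated cells and at 300.3 FPKM on day 1. It then ranged from 313 FPKM on day 2 to 652 FPKM on day 6 and was at 559 FPKM on day 7. On the log2 scale the difference from untreated cells was 6.76 on day 1 and 7.66 on day 7. The increase came mostly as a step on day 1. The straight-line test did not call it (slope 0.72 ± 0.254 log2 units per day, SE; adjusted p = 0.0648), and it did with weights per day (adjusted p = 0.0233) and without day 1 (0.0465). The labels do not give the species of the cDNA, so the share of these reads that came from the construct is not known.

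Classical markers of both states moved over the course. CDH1 (ENSG00000039068, chromosome 16, 68771128 to 68869445), the E-cadherin gene, fell from 153 to 30.7 FPKM (slope -0.35 ± 0.0401 log2 units per day, SE; adjusted p = 0.000512). EPCAM, an epithelial adhesion molecule, fell from 470.5 to 109.9 FPKM (adjusted p = 0.000525). VIM (ENSG00000026025, chromosome 10, 17270258 to 17279592), which encodes the intermediate filament vimentin, rose from 61.9 to 612 FPKM and was already at 238 FPKM on day 1 (slope 0.42 ± 0.0829, SE; adjusted p = 0.00601). FN1, encoding fibronectin, rose from 50.4 to 266 FPKM (adjusted p = 0.000265). CDH2, the N-cadherin gene, rose from 4.58 to 15.1 FPKM (adjusted p = 0.0365), but its call was lost without the untreated mean, without days 2, 5, 6 or 7, without days 5 and 6 together, and with no filter (adjusted p 0.0541 to 0.263).

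**Figure D1:**
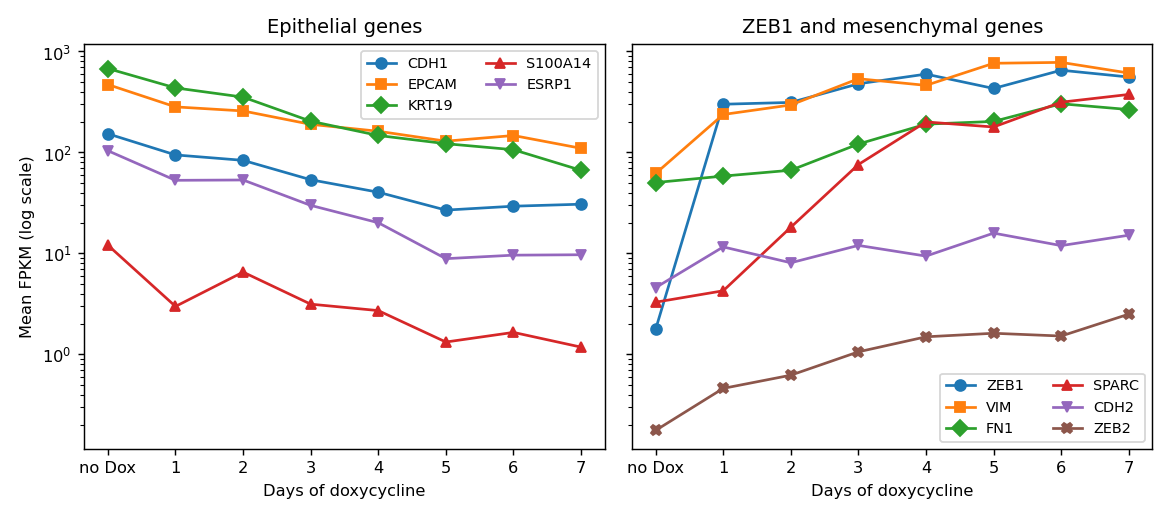
Mean FPKM on a log axis against days of doxycycline for 5 epithelial genes (left) and for ZEB1 and 5 mesenchymal genes (right). Each point is 1 deposited value, read as the authors' mean of 3 libraries. CDH1 falls from 153 to 30.7 FPKM, ZEB1 steps from 1.77 to 300.3 FPKM on day 1, and SPARC climbs from 3.29 to 375 FPKM.

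The number of features at least 2-fold away from untreated cells was then counted for each day, without a test because each day has 1 value. On day 1, 32 features were higher and 68 lower. The counts were 182 and 83 on day 2, 316 and 293 on day 3, 685 and 809 on day 4, 676 and 804 on day 5, 903 and 1132 on day 6, and 681 and 777 on day 7. The share of these features that were higher was 68.7% on day 2 and 51.9% on day 3, and 57.8% and 40.8% after quantile normalization. It was 45.9% on day 4, 45.7% on day 5, 44.4% on day 6 and 46.7% on day 7. The direction with more features depended on the processing on days 3 to 7. With median centring the share was 50.2% on day 5 and 52.8% on day 6. With a pseudocount of 0.1 it was 54.2% on day 4, 50.2% on day 5 and 51.1% on day 7, and with length and GC trends removed 49.5% on day 3. All of these counts share the untreated mean and depend on the pseudocount.

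**Figure D2:**
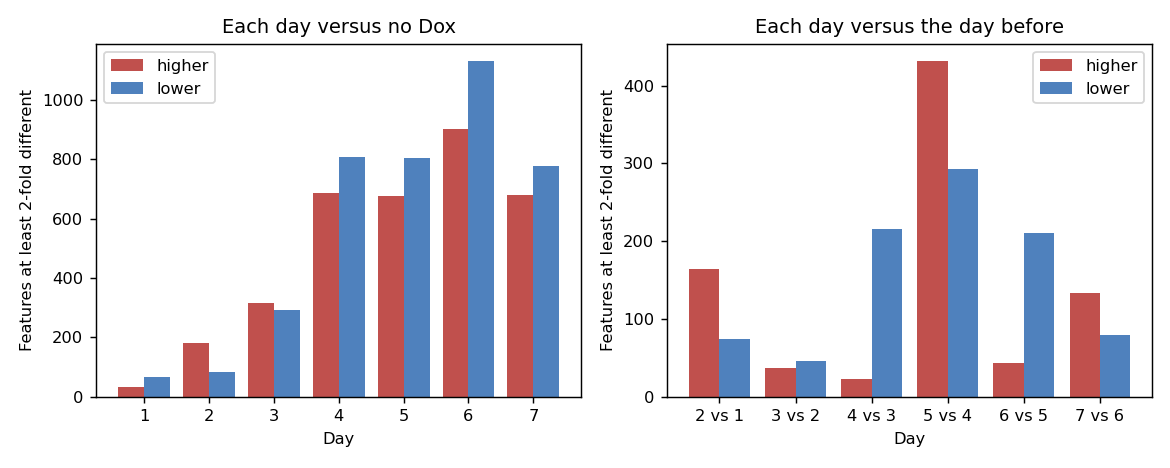
Number of tested features at least 2-fold higher (red) or lower (blue) on the log2(FPKM + 1) scale, for each day against untreated cells (left) and against the day before (right). Day 6 has the most features away from untreated cells, 903 higher and 1132 lower, and the step from day 4 to day 5 has the most of the day-to-day steps, 432 higher and 293 lower.

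Among features that rose, 607 were at least 2-fold higher on day 7. SPARC (ENSG00000113140, chromosome 5, 151040657 to 151066726), a secreted matrix glycoprotein, rose from 3.29 to 375 FPKM, a log2 difference of 6.46 (slope 1.02 ± 0.101, SE; adjusted p = 0.000328). IGFBP7, which binds insulin-like growth factors, rose from 0.760 to 25.9 FPKM, COL3A1, a fibrillar collagen, from 0.0297 to 14.5 FPKM, and LUM, the proteoglycan lumican, from 1.31 to 26.0 FPKM. The collagen-binding integrin subunit ITGA1 rose from 2.44 to 50.5 FPKM and the collagen-internalising receptor MRC2 from 6.62 to 90.2 FPKM. AHRR, the aryl hydrocarbon receptor repressor, rose from 2.66 to 48.4 FPKM, the heparan sulfate proteoglycan SDC3 from 6.27 to 96.3 FPKM, the TGF-beta co-receptor ENG from 0.604 to 19.9 FPKM, and C16orf89 from 0.292 to 13.2 FPKM. Adjusted p for these 10 features lay between 0.000145 and 0.00176.

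Among features that fell, 731 were at least 2-fold lower on day 7. The largest fall was that of CAPN8, a calpain protease, from 42.1 to 0.858 FPKM (log2 difference -4.53; slope -0.67 ± 0.0642, SE; adjusted p = 0.000287). FGFBP1, an FGF carrier protein, fell from 106 to 4.12 FPKM, the membrane protein gene FXYD3 from 125 to 6.46 FPKM, and the transmembrane serine protease TMPRSS4 from 83.2 to 4.78 FPKM. The calcium-binding S100P fell from 55.0 to 3.12 FPKM and S100A2 from 402 to 33.8 FPKM. Keratins were represented by KRT4, from 71.0 to 4.69 FPKM, and KRT19, from 678 to 66.6 FPKM. AGR2, a protein disulfide isomerase of secretory epithelia, fell from 367 to 29.7 FPKM, and ESRP1 (ENSG00000104413, chromosome 8, 95653302 to 95719694), an epithelial splicing regulator, from 104 to 9.70 FPKM. Adjusted p for these 10 features lay between 0.000142 and 0.00193.

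Gene lists fixed before the data were examined were then compared. Of 36 lists, 31 had at least 5 tested members, and limma's camera called 8 up and 12 down over the course with its preset correlation of 0.01. With an estimated correlation, which counts genes that scatter together around their lines as fewer independent genes, camera called 0 lists, with 10 at an unadjusted p under 0.05. Limma's fry, which tests only whether a list's own genes move one way, called 16.

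The epithelial lists were compared first. Of 19 tested genes of adherens and tight junctions, 18 fell, and 18 adjusted over the list alone (camera adjusted p = 9.39e-14, and adjusted p = 0.125 with an estimated correlation). LLGL2, a cell polarity gene, fell from 62.2 to 8.46 FPKM, and the tight junction genes CLDN4 from 175 to 34.1 FPKM and MARVELD3 from 6.97 to 0.591 FPKM. The list's median log2 difference from untreated cells was -0.69 on day 1 and -1.90 on day 7. Among 22 other epithelial genes, 21 fell, and 22 adjusted over the list alone, with a median of -0.84 on day 1 and -2.45 on day 7 (adjusted p = 3.14e-19, and adjusted p = 0.116 with an estimated correlation). RAB25, a vesicle-trafficking GTPase, fell from 116 to 11.4 FPKM and PRSS22 from 30.5 to 3.12 FPKM.

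Of 9 tested desmosome genes 8 fell, and 9 adjusted over the list alone (median -1.21 on day 7; adjusted p = 2.38e-07, and adjusted p = 0.116 with an estimated correlation). JUP, encoding plakoglobin, fell from 72.0 to 16.7 FPKM, DSP, encoding desmoplakin, from 11.2 to 2.56 FPKM, PERP from 60.5 to 14.1 FPKM, and PKP3 from 37.4 to 9.55 FPKM. Of 10 keratins 9 fell, and 9 adjusted over the list alone (median -1.79; adjusted p = 4.71e-08, and adjusted p = 0.0975 with an estimated correlation), among them KRT15 from 11.4 to 1.71 FPKM and KRT81 from 66.6 to 15.2 FPKM. Of 12 epithelial transcription factors 10 fell, and 10 adjusted over the list alone (median -1.84; adjusted p = 1.51e-07, and adjusted p = 0.116 with an estimated correlation). ELF3 fell from 162 to 27.8 FPKM, GRHL2 from 25.8 to 4.15 FPKM, EHF from 4.26 to 0.344 FPKM, and FOXA2 from 20.8 to 4.67 FPKM.

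Mesenchymal markers and matrix genes were called up as lists. Of 22 tested mesenchymal markers 14 rose and 0 fell, and 15 rose adjusted over the list alone, with a median of 0.26 on day 1 and 1.45 on day 7 (adjusted p = 2.37e-07, and adjusted p = 0.0975 with an estimated correlation). MYL9, a myosin light chain of contractile cells, rose from 1.08 to 15.5 FPKM. The list names 32 genes, and its untested members stayed under 1 FPKM on all days. They included ACTA2 (0.346 FPKM untreated, 0.662 FPKM on day 7), PDGFRB (0.0923 and 0.907 FPKM), FSTL1 (0.242 and 0.240 FPKM) and THY1 (0 and 0.00186 FPKM). Of 21 collagen and matrix genes 14 rose and 0 fell, and 15 rose adjusted over the list alone (median 1.08 on day 7; adjusted p = 5.84e-07, and adjusted p = 0.0975 with an estimated correlation). VCAN, encoding versican, rose from 2.499 to 25.3 FPKM, the fibrillin gene FBN1 from 4.14 to 37.3 FPKM, and EFEMP2 from 1.38 to 10.6 FPKM.

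Of 9 genes of the hemidesmosome and its laminin 5 fell and 0 rose, and 6 fell adjusted over the list alone (median -0.94 on day 7; adjusted p = 0.00383, and adjusted p = 0.0975 with an estimated correlation). LAMB3 fell from 83.0 to 24.2 FPKM. LAMA3 fell from 33.5 to 11.2 FPKM, a call lost without the untreated mean, day 1 or days 5 and 6 together, and with no filter (adjusted p 0.0566 to 0.14), and ITGB4 from 60.9 to 21.3 FPKM, a call lost without the untreated mean (adjusted p 0.067). Of 12 integrins 3 rose and 3 fell, or 6 and 4 adjusted over the list alone, and the list was not called (adjusted p = 0.673). ITGB6, an epithelial subunit, fell from 22.1 to 1.67 FPKM, and ITGB3 rose from 0.463 to 2.32 FPKM, a call lost without the untreated mean, without days 1 or 6, without days 5 and 6 together, and with no filter (adjusted p 0.0521 to 0.133). Of 16 extracellular proteases and inhibitors 6 rose and 3 fell, or 6 and 4 adjusted over the list alone, without a call by camera (adjusted p = 0.163) and with one by fry (adjusted p = 0.0198). MMP2, a gelatinase, rose from 0.0656 to 2.95 FPKM, and SERPINB5, encoding maspin, fell from 25.9 to 3.71 FPKM. MMP16 rose from 1.03 to 6.15 FPKM, a call lost without the untreated mean, without days 1, 2, 3 or 7, and with no filter or a filter at 5 FPKM (adjusted p 0.051 to 0.273).

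**Figure D3:**
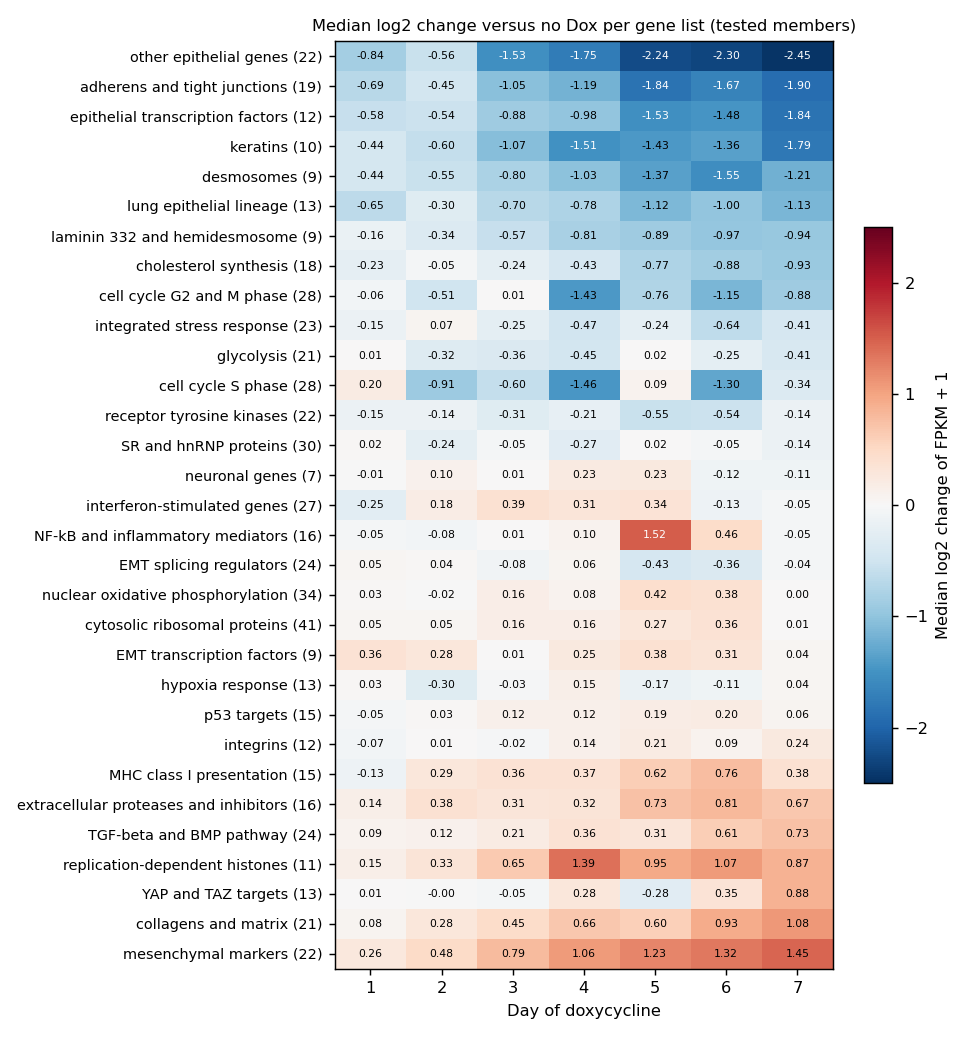
Median log2 difference of FPKM + 1 from untreated cells for the 31 gene lists with at least 5 tested members (number of tested members in brackets) on each day from 1 to 7, with blue for lower and red for higher. Other epithelial genes reach -2.45 and mesenchymal markers 1.45 on day 7, while S phase genes alternate between days.

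Of the EMT transcription factors, ZEB2, the ZEB1 paralog, rose from 0.177 to 2.504 FPKM (adjusted p = 0.000545), and it was the only 1 of 9 tested members called, also adjusted over the list alone. The list was not called by camera (adjusted p = 0.176) and was called up by fry (adjusted p = 0.0149). The 9 members include the induced ZEB1 itself, with a slope of 0.72 per day against a list median of 0.04, and the list was not tested without it. SNAI2 was at 6.74 FPKM in untreated cells and 6.73 FPKM on day 7 (adjusted p = 0.373), SNAI1 at 2.56 and 2.02 FPKM (0.552, and 0.0252 with an upward slope without day 7). TCF4 was at 2.78 and 7.33 FPKM (0.224, and upward at 0.0277 without days 5 and 6 and at 0.0385 with length and GC trends removed), TCF3 at 45.8 and 47.1 FPKM (0.795), SOX9 at 9.65 and 14.5 FPKM (0.0927, and 0.0228 upward with weights per day), and FOXC1 at 6.11 and 5.57 FPKM (0.884). TWIST1 and TWIST2 were listed at 0 on all 8 days, and PRRX1 stayed under 1 FPKM, at 0.0625 FPKM in untreated cells and 0.461 FPKM on day 7.

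Splicing regulators were a stated interest of the study. Of 24 tested regulators linked to EMT splicing 6 fell and 3 rose, with 6 and 3 adjusted over the list alone, and the list was not called (adjusted p = 0.0768), although it was called down without day 7 (adjusted p = 0.0082, and adjusted p = 0.423 in that fit with an estimated correlation). The epithelial regulators ESRP1 and ESRP2 fell, the latter from 24.6 to 4.79 FPKM (adjusted p = 0.0014), as did RBM47, from 69.3 to 27.2 FPKM (0.000998), and PTBP3, from 48.0 to 21.5 FPKM (0.00441). CELF4 fell from 1.22 to 0.253 FPKM (0.0248), which did not hold without the untreated mean or days 5 and 6 together (adjusted p 0.0574 to 0.17), and KHDRBS3 from 22.6 to 13.7 FPKM (0.0433), which did not hold without the untreated mean, without days 1, 3, 4, 6 or 7, and with no filter, median centring, quantile normalization or length and GC trends removed (adjusted p 0.0515 to 0.271). KHDRBS2 rose from 1.73 to 3.66 FPKM (0.048), which did not hold without the untreated mean, without days 1, 2, 3, 4, 6 or 7, and with a pseudocount of 0.1, no filter or features listed at 0 kept (adjusted p 0.0501 to 0.17). NOVA1 rose from 5.28 to 9.20 FPKM (0.0464), which did not hold without the untreated mean, without days 1, 3, 4, 6 or 7, without days 5 and 6 together, and with no filter (adjusted p 0.0525 to 0.29), and CELF5 from 0.538 to 1.44 FPKM (0.0278), which did not hold without the untreated mean or day 6, and with no filter (adjusted p 0.0516 to 0.153).

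The mesenchymal-associated splicing regulators QKI, RBFOX2 and MBNL1 were not called. QKI was at 23.2 FPKM in untreated cells, 34.8 on day 4, 19.7 on day 5, 21.0 on day 6 and 34.0 on day 7 (adjusted p = 0.946). RBFOX2 was at 49.7, 53.5, 36.6, 41.1 and 54.0 FPKM on the same days (0.51). MBNL1 was at 46.3, 46.8, 25.3, 30.2 and 55.1 FPKM (0.443, and 0.0367 with a downward slope without day 7). MBNL2 was at 38.8 FPKM on day 4 and 18.0 FPKM on day 5, MBNL3 at 6.91 and 3.48 FPKM, MSI2 at 50.8 and 22.3 FPKM, and CELF1 at 41.1 and 27.2 FPKM, all without a called trend. Day 7 minus untreated log2 differences were -0.03 for PTBP1, 0.20 for PTBP2, -0.10 for CELF2, 0.06 for ELAVL2, -0.10 for KHDRBS1, -0.20 for RBM38, 0.54 for TIA1 and -0.18 for TIAL1, none of them called in the main test. CELF2 and ELAVL2 were called down without day 7 (adjusted p = 0.00761 and 0.00699) and with weights per day (0.0118 and 0.0156), as was PTBP1 with weights per day (0.049). Of 30 SR and hnRNP proteins 2 rose, with 0 adjusted over the list alone, and the list was not called (adjusted p = 0.922). HNRNPH2 rose from 41.8 to 54.9 FPKM, a call lost without the untreated mean, without days 1, 2 or 6, without days 5 and 6 together (adjusted p 0.0582 to 0.144), and SRSF5 rose from 195 to 255 FPKM, a call lost without the untreated mean, without days 1 or 6, without days 5 and 6 together (adjusted p 0.0528 to 0.0593). Day-specific deviations of long and short transcripts differed in this table, with a rank correlation between transcript length and the deviation from the line, across 14904 features, of -0.322 on day 5, -0.382 on day 6 and 0.389 on day 7. Genes are not independent replicates, so no p is given.

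**Figure D4:**
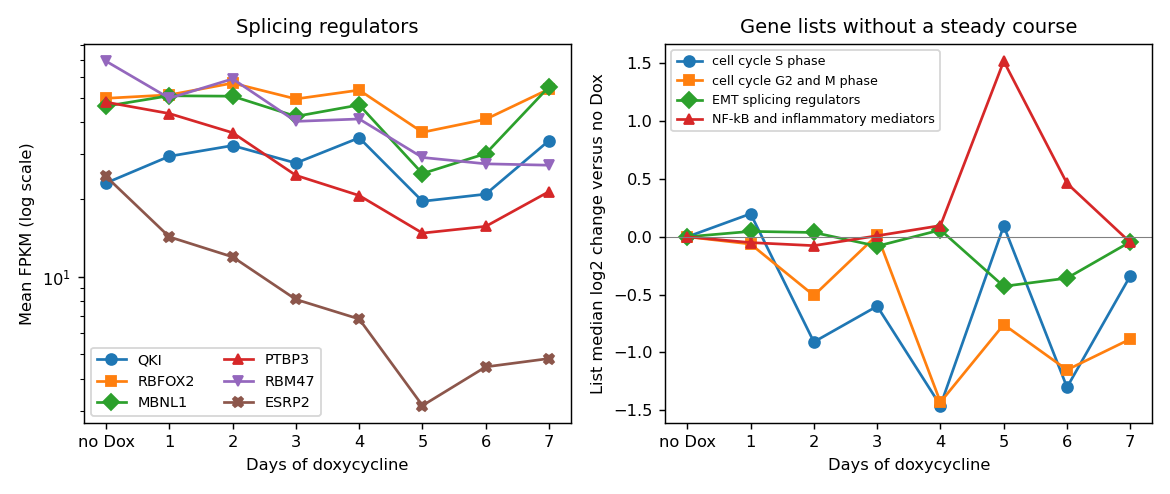
Left, mean FPKM on a log axis of 6 splicing regulators against days of doxycycline. Right, median log2 difference from untreated cells of 4 gene lists. ESRP2 falls from 24.6 to 4.79 FPKM, QKI is at 34.8 FPKM on day 4 and 19.7 FPKM on day 5, and the S phase median moves from -1.46 on day 4 to 0.09 on day 5.

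Signalling lists were examined next. Of 24 genes of the TGF-beta and BMP pathway 11 rose and 0 fell, or 16 and 1 adjusted over the list alone (median 0.73 on day 7; adjusted p = 8.5e-07, and adjusted p = 0.0975 with an estimated correlation). The targets ID3 and ID2, inhibitors of basic helix-loop-helix factors, rose from 20.5 to 182 FPKM and from 8.61 to 64.4 FPKM, with their highest values on day 6 (294 and 90.2 FPKM). SMAD6, an inhibitory SMAD, rose from 7.70 to 23.6 FPKM, and the ligand gene TGFB1 from 10.6 to 28.6 FPKM, a call lost without the untreated mean (adjusted p 0.064). Of 13 YAP and TAZ targets 5 rose and 0 fell, with 5 adjusted over the list alone (adjusted p = 0.0214, and adjusted p = 0.514 with an estimated correlation), and the list's call was lost without day 7, and with fry (adjusted p 0.0759 to 0.478). CTGF rose from 2.29 to 23.7 FPKM and ARHGEF17 from 7.72 to 27.7 FPKM, and CYR61 rose from 15.2 to 44.8 FPKM, a call lost without days 1, 2, 3, 4, 6 or 7, and with a pseudocount of 0.1, no filter, eBayes without trend, robust eBayes, weights per day, short RNA features kept, features listed at 0 kept or length and GC trends removed (adjusted p 0.0504 to 0.233).

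Receptor tyrosine kinases and lung lineage genes were called down as lists. Of 22 receptor tyrosine kinases 8 fell and 3 rose, with the same counts adjusted over the list alone (adjusted p = 0.0382, and adjusted p = 0.507 with an estimated correlation), and the call was lost without the untreated mean, without days 2, 5 or 6, without days 5 and 6 together, and with no filter (adjusted p 0.0507 to 0.256). EPHA1 fell from 10.3 to 0.853 FPKM, ERBB3 from 21.7 to 3.16 FPKM, and FGFR3 rose from 1.33 to 7.71 FPKM. AXL rose from 1.72 to 8.50 FPKM, a call lost without the untreated mean, without days 2, 3, 6 or 7, and with no filter (adjusted p 0.0606 to 0.186). Of 13 lung epithelial lineage genes 7 fell and 2 rose, with the same counts adjusted over the list alone (adjusted p = 0.0213, and adjusted p = 0.53 with an estimated correlation), and that call was lost without the untreated mean or day 7, and with no filter or a filter at 5 FPKM (adjusted p 0.0701 to 0.21). MUC5B fell from 10.02 to 0.768 FPKM and MUC16 from 5.31 to 0.884 FPKM, both mucins, while the falls of MUC1, from 15.3 to 2.67 FPKM, and of the homeodomain gene HOPX, from 42.4 to 8.05 FPKM, were not called without the untreated mean (adjusted p 0.063 and 0.0822), nor was HOPX without days 5 and 6 (0.0697).

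Cell cycle genes were lower on some days. The median of 28 S phase genes was 0.20 on day 1, -0.91 on day 2, -0.60 on day 3, -1.46 on day 4, 0.09 on day 5, -1.30 on day 6 and -0.34 on day 7. The list was called down (adjusted p = 0.0399, and adjusted p = 0.738 with an estimated correlation) although 0 of its members had a called trend, also adjusted over the list alone, and the call was lost without the untreated mean, without days 1 or 6, and with a filter at 5 FPKM or fry (adjusted p 0.0553 to 0.493). Of 28 G2 and M phase genes 11 fell, and 21 adjusted over the list alone (median -1.43 on day 4 and -0.88 on day 7; adjusted p = 2.37e-07, and adjusted p = 0.507 with an estimated correlation), and the list was not called by fry (adjusted p = 0.0776). The mitotic genes HMMR and BUB1 fell from 46.5 to 18.7 FPKM and from 52.5 to 24.1 FPKM, and neither was called without the untreated mean (adjusted p 0.0511 and 0.0674) or without days 5 and 6 (0.057 and 0.083). DLGAP5 fell from 56.9 to 24.8 FPKM, a call lost without the untreated mean, without days 1 or 6, without days 5 and 6 together, and with no filter (adjusted p 0.0588 to 0.108), and CDC25C fell from 18.7 to 7.80 FPKM, a call lost without the untreated mean, without days 1 or 6, without days 5 and 6 together, and with no filter (adjusted p 0.063 to 0.116).

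Lists of metabolism and stress were compared in the same way. Of 18 tested cholesterol synthesis genes 13 fell and 0 rose, and 15 fell adjusted over the list alone (median -0.93 on day 7; adjusted p = 2.87e-09, and adjusted p = 0.0975 with an estimated correlation). MVK, mevalonate kinase, fell from 26.0 to 6.45 FPKM, FDFT1, squalene synthase, from 147 to 42.2 FPKM, and the sterol sensor INSIG1 from 46.3 to 13.5 FPKM. Of 23 genes of the integrated stress response 10 fell and 1 rose, or 14 and 1 adjusted over the list alone (median -0.41; adjusted p = 0.00013, and adjusted p = 0.44 with an estimated correlation), with CTH falling from 23.3 to 7.62 FPKM and TRIB3 from 45.6 to 18.8 FPKM. SLC7A11 fell from 13.2 to 6.20 FPKM, a call lost without the untreated mean, day 6 or days 5 and 6 together, and with no filter (adjusted p 0.051 to 0.106), and ATF3 fell from 12.4 to 5.98 FPKM, a call lost without day 6 (adjusted p 0.0517).

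Glycolysis was not called (adjusted p = 0.153, and 0.0151 downward without days 5 and 6, where the adjusted p = 0.54 with an estimated correlation). In it 2 of 21 genes fell and 1 rose, with the same counts adjusted over the list alone, and HK2, a hexokinase, fell from 20.6 to 9.56 FPKM. SLC2A3 rose from 0.574 to 5.40 FPKM, a call lost without the untreated mean, and with no filter (adjusted p 0.0516 to 0.115), and LDHA fell from 833 to 363 FPKM, a call lost without the untreated mean, without days 1 or 6, without days 5 and 6 together, and with no filter (adjusted p 0.0563 to 0.191). Of 13 hypoxia response genes 3 fell and 1 rose, or 3 and 2 adjusted over the list alone, without a call (adjusted p = 0.481), and VEGFA fell from 147 to 62.7 FPKM. PDK1 fell from 9.98 to 5.08 FPKM. BNIP3 fell from 41.9 to 27.9 FPKM, a call lost without the untreated mean, without days 1, 3, 4, 5 or 6, without days 5 and 6 together, and with no filter, median centring or quantile normalization (adjusted p 0.0535 to 0.253), and P4HA2 rose from 15.8 to 28.3 FPKM, a call lost without the untreated mean, without days 1, 3, 4, 5 or 6, without days 5 and 6 together, and with no filter, features listed at 0 kept or length and GC trends removed (adjusted p 0.0503 to 0.268).

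Nuclear genes of oxidative phosphorylation and cytosolic ribosomal proteins were called up by small changes that peaked on days 5 and 6. Of 34 oxidative phosphorylation genes 2 rose, with 0 adjusted over the list alone (adjusted p = 0.0309, and adjusted p = 0.738 with an estimated correlation). UQCRC2 rose from 40.9 to 64.9 FPKM, a call lost without the untreated mean, without days 1, 3 or 6, without days 5 and 6 together, and with no filter (adjusted p 0.0545 to 0.153), and NDUFA10 rose from 49.5 to 65.7 FPKM, a call lost without the untreated mean, without days 1 or 6, without days 5 and 6 together (adjusted p 0.0626 to 0.119). The list median was 0.42 on day 5, 0.38 on day 6 and 0.00 on day 7. Of 41 ribosomal proteins 0 had a called trend, also adjusted over the list alone (adjusted p = 0.0309, and adjusted p = 0.738 with an estimated correlation), and the median was 0.27 on day 5, 0.36 on day 6 and 0.01 on day 7. The first call was lost without days 2, 5 or 6, and with fry (adjusted p 0.0615 to 0.314), and the second without the untreated mean, without days 2, 5 or 6, and with no filter, quantile normalization or fry (adjusted p 0.0592 to 0.316). Without days 5 and 6 both lists pointed down, each with an adjusted p of 0.99. The deviations from the line on days 5, 6 and 7 had rank correlations with transcript length of -0.322, -0.382 and 0.389 across all features with a length, and with GC content of 0.270, 0.309 and -0.365. With length and GC trends removed, the medians on these days were 0.40, 0.28 and -0.01 for oxidative phosphorylation and 0.21, 0.33 and 0.06 for ribosomal proteins.

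Day 1 was then compared with untreated cells, with 1 value on each side and no test of the difference itself. After ZEB1, the largest increases were those of ARHGEF26-AS1, from 0.782 to 8.67 FPKM, the noncoding RNA RMRP, from 7.08 to 42.2 FPKM, VIM, and the collagenase MMP13, from 28.3 to 82.4 FPKM. The pseudogenes TMSB4XP2, from 0.275 to 2.34 FPKM, and COX7CP1, from 8.74 to 22.0 FPKM, can share reads with their parent genes. The others were MMP9, from 0.766 to 3.41 FPKM, UBD, from 1.01 to 3.72 FPKM, and CPA4, from 0.490 to 2.48 FPKM. Of these 10, only VIM was called by the main trend test. ZEB1 was called up with weights per day (adjusted p = 0.0233) and without day 1 (0.0465), TMSB4XP2 up with weights per day (0.0317) and without day 7 (0.028), and ARHGEF26-AS1 down without the untreated mean (0.023).

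The largest decreases on day 1 included 7 features that also fell over the course. They were KRT16P2 (a keratin pseudogene, log2 difference -1.94), SPTSSB (-1.80), HOPX (-1.72), S100A14 (-1.71), ATP2C2 (-1.64), TMEM125 (-1.56) and the channel-activating protease PRSS8 (-1.47). Without the untreated mean the calls of HOPX (adjusted p = 0.0822), S100A14 (0.0509) and TMEM125 (0.0577) were lost, and without days 5 and 6 those of KRT16P2 (0.0576) and HOPX (0.0697). HPX, encoding hemopexin, was at 4.61 FPKM in untreated cells and 0.0900 FPKM on day 1, without a called trend (adjusted p = 0.227). The remaining features were EEF1B2, from 503.8 to 178 FPKM, and NDUFS1, from 50.6 to 17.8 FPKM, which overlap on chromosome 2 and stood at 0.354 and 0.351 of their untreated values. For this pair, failed estimates of single libraries cannot be told from a decrease.

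The time at which features approached their day 7 level was compared between the sets that rose and fell and were at least 2-fold different on day 7. By day 1, 10 of 607 rising features (1.65%) and 82 of 731 falling features (11.2%) had passed 50% of their day 7 difference, and by day 3 these numbers were 428 and 510. The difference between these sets was not tested, and both use the same untreated mean. The sets were selected by a straight line over day, which disfavours features that step on day 1, and adding 1 to FPKM damps early changes of features that start low. The counts therefore do not time rising against falling features.

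Day-to-day steps were compared directly, again without a test. At least 2-fold higher and lower features numbered 164 and 74 from day 1 to day 2, 37 and 46 from day 2 to day 3, 23 and 216 from day 3 to day 4, 432 and 293 from day 4 to day 5, 44 and 211 from day 5 to day 6, and 134 and 80 from day 6 to day 7. From day 1 to day 2 the heat shock gene HSPA6 increased most, from 9.23 to 66.3 FPKM, followed by ENG (2.33 on the log2 scale) and IFITM2 (2.30), and the S phase genes CCNE2 (18.4 to 4.45 FPKM) and GINS2 (39.4 to 12.2 FPKM) and FAM111B (15.3 to 4.71 FPKM) decreased most. SPARC and LUM led the next step, by 2.01 and 1.66 on the log2 scale, and CAPN8 (-1.68) and the transglutaminase TGM2 (-1.48) went down. From day 3 to day 4 ITGA1 (1.43) and SPARC (1.39) were higher, and the cell cycle gene CDCA3 (-1.86) and the helicase PIF1 (-1.68) lower. The immunoglobulin pseudogene IGHVII-43-1 went from 0.381 FPKM on day 2 to 3.09 FPKM on day 3, and the read-through feature DNAJC25-GNG10, listed at 0 on day 6, from 4.01 FPKM on day 3 to 0.282 FPKM on day 4. The overlapping DNAJC25 and GNG10 were left out because they were also at 0 on day 6, so the trend of the read-through feature is not read. POLR2KP1 and ASNSP5 also met the rule for these steps but were listed at 0 on day 3, so no fold is given for them.

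The step from day 4 to day 5 had the most features. UBD, a ubiquitin-like modifier induced by cytokines, went from 1.74 to 40.0 FPKM, the ectonucleotidase ENTPD2 from 0.106 to 10.2 FPKM, and the cytokine gene IL32 from 3.28 to 27.0 FPKM. HSPA6 went from 171 to 17.8 FPKM, LPP from 25.4 to 3.85 FPKM, and SEPP1 from 34.3 to 7.67 FPKM. Over the course SEPP1 rose from 5.45 to 24.3 FPKM, a call lost without the untreated mean, without days 1, 2, 3, 6 or 7, and with no filter (adjusted p 0.0504 to 0.145). From day 5 to day 6, COL3A1 (2.25), SEPP1 (1.66) and FAM189A2 (1.60) increased most, and ENTPD2 (-2.19), EXO1 (-1.99) and RRM2 (-1.99) decreased most. From day 6 to day 7 the largest increases were those of RMRP (2.02), SAMD4A (1.99) and LPP (1.88), and the largest decreases those of IFI30 (-1.91), BECN1 (-1.79) and UBD (-1.78). SAMD4A was called up without days 5 and 6 (adjusted p = 0.0142), IFI30 down without days 5 and 6 (0.00622), and BECN1 up without day 7 (0.023), and none of these 3 was called in the main test. RRM2 was called down with weights per day only (0.0236).

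Some features moved away from their untreated level and had less than 50% of that difference left on day 7. HSPA6 peaked on day 4 at 171 FPKM and was at 4.47 FPKM on day 7, against 6.36 FPKM in untreated cells. UBD (40.0 FPKM), ENTPD2 (10.2 FPKM) and the neutrophil chemokine genes CXCL2 (15.998 FPKM) and CXCL3 (10.1 FPKM) peaked on day 5. In the other direction, the metallothionein gene MT1F was lowest on day 5 (6.02 FPKM, against 40.1 FPKM untreated and 21.0 FPKM on day 7), as was LPP (3.85 FPKM). IMMP1L (12.2 FPKM) and ANKRD36C (1.81 FPKM) were lowest on day 6, and thymidine kinase TK1 on day 4 (32.3 FPKM, against 134 FPKM untreated). None of these 10 was called by the main trend test. With weights per day, CXCL3 was called up (adjusted p = 0.0217) and MT1F (0.00303), ANKRD36C (0.00312), IMMP1L (0.00884), TK1 (0.0292) and LPP (0.0358) down. Without day 7, CXCL3 was called up (0.0445), as it was without days 5 and 6 (0.0276), and MT1F (0.00654), IMMP1L (0.0499) and ANKRD36C (0.00466) down. Without day 5, CXCL2 (0.0414) and CXCL3 (0.0183) were called up, and without day 2, IMMP1L was called down (0.0261).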

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

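The tests of a scale factor per day and of failed estimates of whole loci were chosen after the values they use had been seen. Among features left out of the comparisons, a block of mitochondrial pseudogenes on chromosome 1 went up and down over the days. The ratio of the highest day to untreated cells was 2.80 for MTATP6P1, 2.65 for MTND2P28, 2.73 for MTND1P23, 3.07 for RP5-857K21.7 and 3.09 for RP5-857K21.11, and all 5 were listed at 0 on day 6. MTATP6P1 was at 2016 FPKM in untreated cells, 4260 on day 1, 2336 on day 2, 5645 on day 3, 4008 on day 4, 2384 on day 5 and 2012 on day 7. The other 4 were likewise highest on day 3 and higher on days 1 and 4 than on days 2, 5 and 7. Reads of such copies can be shared with mitochondrial transcripts, which were not analysed here, and the differences between days were not tested.

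The first pattern is the set of 72 features listed at 0 on 1 to 7 days and at 1 FPKM or more on all remaining days. Of these, 22 reached at least 20 FPKM. Many were at 0 on several days, with between 36 (day 3) and 50 (day 6) of the 72 at 0 on a given day. The short pseudogene RPL39P38 (chromosome 19, 18396156 to 18396306) was at 0 on 7 days and at 1.03 FPKM on day 2. PAICS was at 0 in untreated cells and on days 1, 4 and 6 and between 56.7 and 62.8 FPKM on the other days, and the overlapping genes SHC1 and PYGO2 were both at 0 on days 4, 5 and 6. Of the 72 features, 13 had another within 100 kb at 0 on the same days, against a median of 2 and a highest of 9 in 1000 random reassignments of the zero days. These 13 form only 3 blocks, 1 of 9 features on chromosome 1 that holds the mitochondrial pseudogenes, and the pairs SHC1 with PYGO2 and DNAJC25 with GNG10. The other 59 had no such neighbour. Failed estimates of whole loci in the authors' quantification stay open for the 3 blocks, and for the 59 these values do not decide. No biological explanation was tested. The overlapping EEF1B2 and NDUFS1 were kept in the tests. They stood at 0.354 and 0.351 of their untreated value on day 1, 0.288 and 0.313 on day 2, and 0.637 and 0.638 on day 3. On day 4 the shares were 0.273 and 0.320, on day 5 0.325 and 0.340, on day 6 0.294 and 0.268, and on day 7 0.516 and 0.609. Values per library were not used here, so failed estimates of single libraries would not be seen, and no cause was tested.

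The second pattern is the lower level of EMT splicing regulators on days 5 and 6 than on days 4 and 7, with a median difference of -0.41 on the log2 scale over 24 genes, 19 of them lower. The list median lay at percentile 0.03 of random lists matched on transcript length and GC content. The list and the days were picked because of this dip, so the percentile cannot decide whether both are the whole cause. Removing their trend reduced the median difference to -0.20, so a part of the size may come from them. A scale factor per day is argued against by the median difference of all tested features, 0.0203, with the list at -0.39 after quantile normalization. The state of the cells on these days stays open, as untested. Length and GC content stay open too, and so does a deviation of the libraries of days 5 and 6 in other properties.

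The third pattern is the alternation of S phase genes, lower on days 2, 4 and 6 than on days 1, 3, 5 and 7, with all 28 genes lower and a median difference of -1.03. The G2 and M phase list differed by -0.61 between the means of these days, also with 28 of 28 genes lower. Its median went down and up at alternate steps too, but on days 5 and 7 (-0.76 and -0.88) it lay below that of day 2 (-0.51). Length and GC content are argued against by a median difference of -1.02 after removing their trend. The list median lay at percentile 0 of matched random lists (27 of the 28 genes have a length), but the list and the days were picked from these values. A scale factor per day is argued against by the median difference of all tested features, 0.0183. What stays open is the growth state of the cultures on each day, including any difference in density or feeding, which the labels used here do not give; it was not tested. In random lists matched on mean expression the S phase median also lay at percentile 0.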

How the results depend on the processing

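Of the alternatives here, the exact Spearman test, the inclusion of features listed at 0, the omission of days and the removal of length and GC trends were chosen after the data were seen. No paired analysis was possible because the table holds 1 value per day, read as a mean, and no value per library. For the same reason the fit of 2 groups alone and the omission of each library were not run. Without a replicate error and with unknown depth, small differences and low features carry the least certainty.

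The counts of rising and falling features (1822 and 1806) moved by more than 1.5 times with weights per day (3463 and 3152), with the exact Spearman test (789 and 933), without the untreated mean (636 and 804), without day 1 (1044 rising), without day 6 (1030 and 1117) and without day 7 (2801 rising). The 8 lists called up and 12 called down became 0 and 0 with an estimated correlation, and 5 lists were called up without days 5 and 6. Rising and falling features numbered 1721 and 1781 without day 4, and 1838 and 1827 without day 5. These fits have as few days as the other fits without 1 day. However, days 4 and 5 lie in the middle of the course, and leaving out a day near its ends also narrows the spread of the days. A slope is then less precise, so the comparison cannot tell this from other causes of the shifts. The cause of the shifts was not tested.

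Fold counts depended on the pseudocount, which by its construction shrinks changes of low features. With 0.1 in place of 1, features at least 2-fold different from untreated cells numbered 300 on day 1, 806 on day 2, 1339 on day 3, 2471 on day 4, 2418 on day 5, 3072 on day 6 and 2303 on day 7. For the steps they numbered 692 to day 2, 325 to day 3, 466 to day 4, 1450 to day 5, 527 to day 6 and 591 to day 7. With 0.5 they numbered 163 on day 1 and 436 on day 2, and 391, 151 and 336 for the steps to days 2, 3 and 7. Removing the length and GC trends gave 142 for the step to day 7, and the cause was not tested.

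Directions reversed for 4 results, where only results with a call in the main fit or in the alternative could count. SAMD4A had a slope of 0.116 log2 units per day without days 5 and 6, BECN1 a slope of 0.141 without day 7, and the nuclear oxidative phosphorylation and ribosomal protein lists pointed down without days 5 and 6 (adjusted p = 0.99 for both). Among results of lists over these alternatives, 594 stayed on the same side of the threshold, 51 lost and 4 gained a call. The 2 lists that reversed also lost their calls and are not among these 51. Direction was not compared where neither fit made a call. Among trends of named genes 4127 stayed on the same side of the threshold, 278 lost and 31 gained a call. SAMD4A and BECN1 gained a call on reversing and are not among these 31. Of the losses, 59 came with the exact Spearman test, where ESRP1 and ENG were at an adjusted p of 0.0502. A further 44 came without the untreated mean. A log2 change of a named gene counted as moved when it shifted by at least the gene's residual SD around its line. That is a wide margin for features with a step or a peak. By this rule 75 changes moved and 2050 stayed. Of the moves, 49 came under a pseudocount of 0.1, 19 under 0.5, 5 with quantile normalization and 2 (MUC5B and MUC16) with length and GC trends removed. The filters and the keeping of short RNA features or features listed at 0 do not alter a gene's log2 value. Summing entries alters only shared symbols. Cases under these settings therefore say little about stability. The call of receptor tyrosine kinases was lost with no filter (adjusted p = 0.198), that of lung lineage genes with no filter (0.0758) and at 5 FPKM (0.21), and that of S phase genes at 5 FPKM (0.0553).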

Other observations

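The trend test on day means and the test on orders of the days were chosen after the table was seen. Immune gene lists were compared in the same way as the others. Of 16 NF-kB and inflammatory mediators 0 rose and 1 fell, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.288), but its median was 0.10 on day 4, 1.52 on day 5, 0.46 on day 6 and -0.05 on day 7, with CXCL2, CXCL3 and IL32 among its members. LIF, a cytokine of the IL-6 family, fell from 13.7 to 4.36 FPKM. Of 15 genes of MHC class I presentation 6 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.0175, and adjusted p = 0.517 with an estimated correlation), and the call was lost without days 5 and 6 together, and with fry (adjusted p 0.108 to 0.112). TAPBP, encoding tapasin, rose from 30.3 to 58.5 FPKM. ERAP1 rose from 14.2 to 27.0 FPKM, a call lost without the untreated mean (adjusted p 0.0995). PSMB10 rose from 25.7 to 44.5 FPKM, a call lost without the untreated mean or day 6 (adjusted p 0.056 to 0.0975). NLRC5 fell from 18.9 to 9.48 FPKM, a call lost without the untreated mean, day 6 or days 5 and 6 together (adjusted p 0.0722 to 0.167). Of 27 interferon-stimulated genes 6 rose and 3 fell, with the same counts adjusted over the list alone, without a call (adjusted p = 0.671), and USP18 fell from 16.2 to 8.02 FPKM. IFI44L rose from 11.8 to 31.2 FPKM, a call lost without the untreated mean, without days 1 or 2, without days 5 and 6 together, and with no filter (adjusted p 0.0523 to 0.112). STAT2 rose from 20.4 to 50.6 FPKM, a call lost without the untreated mean, without days 1 or 6, and with no filter (adjusted p 0.0546 to 0.116). IFI6 rose from 31.5 to 63.4 FPKM, a call lost without the untreated mean, without days 1, 2 or 6, without days 5 and 6 together, and with no filter (adjusted p 0.0699 to 0.159).

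Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, had a median above untreated cells on days 1 to 7. Of 11 tested members 7 rose and 0 fell, and 8 rose adjusted over the list alone (median 1.39 on day 4 and 0.87 on day 7; adjusted p = 0.000366, and adjusted p = 0.469 with an estimated correlation). HIST1H4H rose from 2.18 to 9.29 FPKM and HIST1H3H from 2.09 to 7.89 FPKM. HIST1H2AC rose from 7.83 to 24.4 FPKM, a call lost without the untreated mean, day 1 or days 5 and 6 together, and with no filter (adjusted p 0.0534 to 0.114), and HIST2H2BE rose from 14.4 to 29.6 FPKM, a call lost without the untreated mean or days 5 and 6 together (adjusted p 0.0594 to 0.0706). Of 15 p53 targets 3 rose and 3 fell, or 4 and 3 adjusted over the list alone, without a call (adjusted p = 0.4), and the apoptosis gene BBC3 rose from 6.61 to 27.7 FPKM. TP53INP1 rose from 1.26 to 7.98 FPKM, a call lost without the untreated mean, without days 1 or 6, and with no filter (adjusted p 0.0698 to 0.14). PHLDA3 fell from 13.1 to 3.65 FPKM, a call lost without the untreated mean (adjusted p 0.0707), and FAS fell from 2.70 to 1.28 FPKM, a call lost without the untreated mean, without days 1 or 6, without days 5 and 6 together, and with no filter (adjusted p 0.0573 to 0.158).

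Of 7 neuronal genes 2 rose, with 2 adjusted over the list alone, without a call (adjusted p = 0.542). MAP2 rose from 4.26 to 14.1 FPKM, a call lost without the untreated mean, without days 1, 2, 3, 6 or 7, and with a pseudocount of 0.1, a pseudocount of 0.5, no filter, a filter at 5 FPKM, robust eBayes, short RNA features kept or features listed at 0 kept (adjusted p 0.051 to 0.171), and SYP rose from 0.380 to 0.9998 FPKM, a call lost without the untreated mean (adjusted p 0.076). Muscle genes had 4 tested members, of which MYL1 rose from 0.0386 to 2.08 FPKM and MB, the myoglobin gene, fell from 58.7 to 5.49 FPKM, and TNNT1 fell from 84.7 to 46.6 FPKM, a call lost without the untreated mean, without days 1, 2, 3, 4, 5 or 7, and with no filter, median centring, eBayes without trend or weights per day (adjusted p 0.0508 to 0.19). Markers of other cell types were mostly under 1 FPKM on all days. Leukocyte markers had 4 tested members, of which LYZ rose from 0.165 to 0.975 FPKM and CORO1A fell from 38.2 to 4.84 FPKM, while PTPRC was at most 0.441 FPKM. Endothelial markers and erythroid and hepatocyte markers had 1 tested member each, without a called trend (1 endothelial member fell adjusted over the list alone), with VWF at most 0.295 FPKM and ALB at most 0.852 FPKM.

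The number of called features was compared between 100 drawn orders of the days, the real one included. The real order called 3628 features and was the only 1 of the 100 to reach that number. The highest other order called 62, and its absolute Spearman correlation with the real order was 0.83. Of the others, 97 called 0. Independent day means in a random order are therefore argued against as the source of the count. Drawing orders treats the days as exchangeable, while neighbouring days need not be independent. A smooth drift over successive days would also make the real order stand out, so the comparison cannot tell an effect of doxycycline from such a drift.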
